A study of Drosophila melanogaster with 18 samples.

How the data were processed

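The data were RNA-seq of whole flies of Drosophila melanogaster at 5 days of age, from 6 groups (F0, INT and NINT in each sex) with 3 libraries each. Total RNA was extracted with Trizol and libraries were made with a stranded kit, per the labels. The deposited tables, 1 for each sex, held counts: raw read counts per gene, not normalised. Each table had 16747 entries with 16727 distinct gene symbols, of which 17 symbols stood at more than 1 locus. The submitters' processing notes name the genome build dm6 and DESeq2, without versions, and the aligner, the counting tool and the strand setting are not given in the sources used here. The tables give a position and a transcript accession per gene, and 16531 entries were matched to a gene of the reference annotation of dm6 used for coordinates, while 216 were not. The near-identical genes Met75Ca and Met75Cb hold identical counts in all 18 libraries, and how reads that fit several genes were counted is not given. Values of such genes, of overlapping genes and of antisense RNAs are uncertain. There were 109 ribosomal RNA entries and 0 entries of the mitochondrial genome.

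Counts were analysed with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1, DESeq2 1.42.0), and tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. For each sex the 9 libraries were fitted together with 1 coefficient per group, TMM scaling, genes kept by filterByExpr on the groups (minimum count 10, minimum total count 15) and the quasi-likelihood test, which is two-sided. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The comparisons were INT with NINT, INT with F0 and NINT with F0 in each sex. A fit of the 18 libraries gave the difference of INT and NINT over both sexes and its interaction with sex, defined as the log2 fold change in females minus that in males. Fold changes are of the first group over the second. Levels are counts per 1e6 counts (CPM) with TMM-scaled library sizes for named genes, and plain CPM for the library checks of yolk protein genes, Act88F, roX1 and Acp36DE; logarithms used a prior count of 2. A fold against a group at 0 counts was computed against a floor of 3 counts over the group, and where a group held 1 to 3 counts the ratio is given with an exact binomial interval of 95%. Such intervals, floors and the Wilson intervals of count shares cover counting error only.

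Gene lists were 13 sets of tissue markers (neurons, glia, muscle, fat body, midgut, Malpighian tubule, hemocytes, eye, testis, male accessory gland, ejaculatory duct and bulb, ovary, female reproductive tract) and 31 sets by function. The latter covered learning and memory, synaptic vesicle and active zone, acetylcholine and monoamine, insulin and TOR signalling, lifespan and antioxidant, glutathione transferase and cytochrome P450, heat shock and chaperone, antimicrobial peptide and bomanin, immune recognition and melanization, Turandot stress, yolk with vitelline and chorion, accessory gland seminal fluid, testis and sperm, digestive enzyme, respiratory chain and ATP synthase, mitochondrially encoded, cytosolic ribosomal protein, muscle structural, circadian, phototransduction, odorant-binding and chemosensory, lipid metabolism, fat body storage and secreted, cuticle protein, piRNA pathway, DNA replication and cell cycle, autophagy, proteasome, glycolysis and tricarboxylic acid cycle, founder genotype (w, mwh and flr, named in the founder strains), and germline and female gonad genes. The mitochondrially encoded list had 0 members in the tables, so 43 lists were tested. Each list was tested with camera with a preset correlation of 0.01 between genes, and adjusted p-values are over the 43 lists of a comparison. camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way, were run beside it. With an estimated correlation no list was called in any comparison except cuticle protein genes in the interaction. A count adjusted over the list alone corrects for the members of that list only.

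Named genes were taken by a fixed rule. In each comparison by sex they were called genes with groups that did not overlap and a mean of at least 5 CPM in 1 group, the 6 largest rises and 6 largest falls (3 and 3 against F0), then called members of the gene lists by p, up to 16 genes (8 against F0), and further members of called lists with the largest fold changes. In the fits over both sexes the 5 smallest p in each direction were taken. The comparisons, tests, lists, naming rule and the further fits listed next were fixed before the data were examined. Act88F and the Yp1, Yp2 and Yp3 sum were chosen as library checks after the data were seen.

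The further fits fixed in advance were the DESeq2 test, RLE scaling in edgeR, no filter on low counts, a filter of 5 CPM in 3 libraries, ribosomal RNA left out, the replicate number as a block, a limit of 2-fold on the fold change of called genes, a fit of the 6 compared libraries or of all 18, each library left out in turn, and the other list tests. Fits chosen after the data were seen left out the 4 male libraries above 500 CPM of yolk protein genes, the 3 female libraries above 1000 CPM of Act88F, or 116 entries of ribosomal DNA loci, SteXh and 7SL RNA. Where a fit left 1 library in a group, that library was assumed to vary like those of the other groups. RLE scaling moved the median log2 fold change of all genes by -0.101 in the interaction, and in the fit of all 18 libraries the median for NINT against F0 males moved by -0.113.

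The fits were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. For INT against NINT edgeR recovered 12% of the former and 70% of the latter in males with 3 false calls, and 16% and 71% in females with 4 false calls. DESeq2 recovered 38% and 85% in males with 39 false calls, and 45% and 90% in females with 45 false calls. For the interaction edgeR recovered 3% and 50%.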

Results

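RNA was sequenced from whole 5-day-old fruit flies of a founder population (F0) and of groups named INT and NINT, both taken at generation F12. Each group was sampled in both sexes with 3 libraries per group and sex, which gave 18 libraries. The labels name 10 strains and do not spell out INT and NINT, and the series title concerns intelligence and longevity. Male libraries held 31.8 to 39.2 M counts. Female libraries held 50.2 to 58.3 M counts in F0, 31.6 to 35.4 M in INT and 40.9 to 47.2 M in NINT. Replicates of a group differed by more than counting error, with a chi-square per gene of 53.4 to 1230 between pairs of replicates. The labels do not say whether the replicates came from separate cultures or cohorts, so the p-values may measure technical spread only.

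Several measures set single libraries or whole groups apart. Ribosomal RNA genes took 1.84% to 8.8% of the counts in males. In females they took 20.28% to 36.26% in F0, 10.41% to 23.16% in INT and 5.94% to 7.36% in NINT. The 95% Wilson interval of these shares was at most 0.028 percentage points wide in each library. The yolk protein genes Yp1, Yp2 and Yp3, which are known for expression in female fat body and ovary, summed to 1180, 563 and 6.8 counts per 1e6 (CPM) in F0 male replicates 1 to 3. The same sum was 11.3 to 14.7 CPM in the INT males and 136, 809 and 983 CPM in NINT male replicates 1 to 3. In females the sum was 4550 to 23600 CPM. The indirect flight muscle actin gene Act88F was at 2270, 3110 and 262 CPM in F0 female replicates 1 to 3 and at 17.8, 72.2 and 1790 CPM in INT female replicates 1 to 3. In the NINT females it was at 5.33 to 10.5 CPM. NINT female 1 held 71.26 CPM of the seminal fluid gene Acp36DE, against 2.08 to 10.67 CPM in the other females. The male dosage compensation RNA roX1 was at 1044 to 1651 CPM in males and at 2.79 to 39.94 CPM in females.

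**Figure D1:**
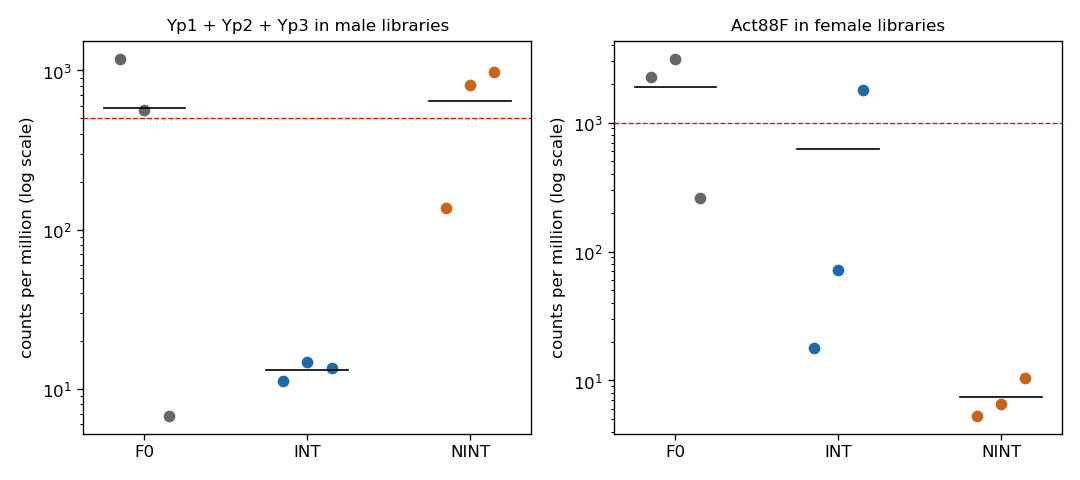
CPM (log axis) of Yp1, Yp2 and Yp3 together in the 9 male libraries and of Act88F in the 9 female libraries. Points are libraries, black lines are group means and red dashed lines mark 500 and 1000 CPM; 4 male libraries lie above 500 CPM and 3 female libraries above 1000 CPM.

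The comparison of INT with NINT males asks which genes differed between the groups in that sex. Antimicrobial genes were lower in INT males. The antimicrobial peptide and bomanin list held 34 measured members, secreted peptides of the humoral immune response, and each of the 34 had a negative fold change, with a median log2 of -1.66. BomS5 (listed as CG15065, 2R, 18389959 to 18390242) was at 34.1 ± 4.86 CPM in INT and 143 ± 10.9 CPM in NINT (SD, n = 3). BomBc1 (listed as IM23, 2R, 18382704 to 18383235) was at 13.1 ± 2.9 against 63.1 ± 17.2 CPM. Seminal fluid genes of the accessory gland lay higher in INT males, with 48 of 50 above 0 and a median log2 of 0.70.

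edgeR called 6 of 15051 genes, and each of these was lower in INT. BomS5 fell by 2.07 on the log2 scale (SE 0.22, adjusted p = 0.03) and BomBc1 fell by 2.27 (SE 0.25, adjusted p = 0.03). CG4757 (3R, 11161207 to 11163129) had a log2 fold change of -2.24 (SE 0.19, adjusted p = 0.016) and CG14245 (3R, 26728727 to 26729119) one of -2.19 (SE 0.21, adjusted p = 0.03). Argl (listed as CG9510, 2L, 8939725 to 8941763), an argininosuccinate lyase by name, was 3.02-fold lower (adjusted p = 0.03). The antisense RNA CR44192 (3R, 10052846 to 10054298) was 4.85-fold lower (adjusted p = 0.049). The strand used for counting is not given in the sources used here, so its reads cannot be assigned to it with certainty. An unadjusted p under 0.05 was reached by 2473 genes, and 3078 genes (20.5%) had groups that did not overlap, where chance gives 10%.

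The antimicrobial peptide and bomanin list fell in INT males (adjusted p = 6.98e-17), with an adjusted p of 0.55 with an estimated correlation. In it 2 members were called over all genes, 18 were called when adjusted over the list alone, and 27 had groups that did not overlap. Members outside the calls included Drs, the gene of drosomycin, at 22.9 ± 8.02 against 159 ± 46.3 CPM (adjusted p = 0.14), Dro at 15.7 ± 10.5 against 130 ± 54.5 CPM (adjusted p = 0.22) and AttA at 16.1 ± 13.6 against 122 ± 43.4 CPM. Immune recognition and melanization genes (median -0.43, 37 of 47 below 0, adjusted p = 0.00175) and hemocyte markers (median -0.60, 10 of 10 below 0, adjusted p = 0.00179) also fell, with an adjusted p of 0.58 for both with an estimated correlation. Both falls rest on INT males 1 and 2. Against the mean of the 9 males the hemocyte markers were at -0.99, -0.81 and 1.12 in INT males 1 to 3 and at 1.01, 0.64 and 0.84 in NINT males 1 to 3. In the former list 0 members were called by edgeR over all genes and 8 when adjusted over the list alone. Fat body storage and secreted genes fell (median -0.49, 23 of 27 below 0, adjusted p = 0.000284; 0.55 as the adjusted p with an estimated correlation).

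Seminal fluid genes rose as a list in INT males (adjusted p = 8.57e-13), as did the markers of the male accessory gland (median 0.96, 10 of 10 above 0, adjusted p = 3.96e-05), with an adjusted p of 0.55 for both with an estimated correlation. Both rises rest on INT males 1 and 2. Against the mean of the 9 males the gland markers were at 0.58, 0.62 and -0.47 in INT males 1 to 3 and at -0.36, -0.69 and -0.43 in NINT males 1 to 3. No seminal fluid gene was called over all genes and 26 of 50 were called when adjusted over the list alone. Genes of nerve cells rose as lists. Synaptic vesicle and active zone genes had 31 of 35 members above 0 (median 0.29, adjusted p = 2.31e-07), neuron markers 10 of 10 (median 0.43, adjusted p = 1.7e-05), eye markers 9 of 10 (median 0.34, adjusted p = 3.96e-05) and phototransduction genes 31 of 35 (median 0.30, adjusted p = 1.55e-06), each with an adjusted p of 0.55 with an estimated correlation. Respiratory chain and ATP synthase genes (72 of 83 above 0, median 0.24, adjusted p = 2.1e-05), muscle structural genes (32 of 36, median 0.27, adjusted p = 0.000284) and proteasome genes (27 of 32, median 0.18, adjusted p = 0.000141) rose as well, with an adjusted p of 0.58 for each with an estimated correlation, and INT male 3 lay with NINT in the respiratory list.

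Cell division, germline and egg lists fell in INT males. DNA replication and cell cycle genes had 40 of 42 below 0 (median -1.24, adjusted p = 8.57e-13, 24 called over the list alone). piRNA pathway genes, which silence germline transposons, had 30 of 33 (median -0.63, adjusted p = 9.02e-08, 5 over the list alone). Both had 0.55 with an estimated correlation and may follow the yolk protein sum. Yolk, vitelline and chorion genes (median -4.96, 25 of 25 below 0, adjusted p = 0.000164), ovary markers (median -5.12, 10 of 10, adjusted p = 0.000786) and germline and female gonad genes (median -0.86, 22 of 28, adjusted p = 0.000246) moved with the Yp1, Yp2 and Yp3 sum of 809 and 983 CPM in NINT males 2 and 3, with an adjusted p of 0.58 for each with an estimated correlation. Ovary markers and germline genes lost their call without INT male 3 (adjusted p = 0.051 and 0.076).

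Weaker list results depended on single libraries. Learning and memory genes (median 0.19, 31 of 40 above 0, adjusted p = 0.000832), acetylcholine and monoamine genes (median 0.18, 26 of 37, adjusted p = 0.00175) and heat shock proteins and chaperones (median 0.45, 26 of 31, adjusted p = 0.00179) rose. Each had an adjusted p of 0.1 without INT male 3, and heat shock genes also had 0.053 without NINT male 2. Acetylcholine and monoamine genes had 0.069 without the 4 libraries above 500 CPM of yolk protein genes. With an estimated correlation the adjusted p was 0.55, 0.55 and 0.58 in that order. Testis and sperm genes rose (median 0.35, 49 of 54, adjusted p = 0.00256; 0.71 as the adjusted p with an estimated correlation) and lost the call without INT male 1 (0.74) or INT male 2 (0.062). Glutathione transferase and cytochrome P450 genes fell (median -0.15, 71 of 115 below 0, adjusted p = 0.000832; 0.66 as the adjusted p with an estimated correlation) and lost the call without INT male 1 (0.13) or INT male 2 (0.065). Fat body markers fell (median -0.88, 7 of 9, adjusted p = 0.0439; 0.55 as the adjusted p with an estimated correlation) and reached an adjusted p of 0.12, 0.058, 0.058, 0.078 and 0.056 without INT males 1, 2 and 3 and NINT males 1 and 2.

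The gene count depended on INT male 3, whose profile was nearest to NINT male 1. Without INT male 3 edgeR called 3956 genes, 1732 higher and 2224 lower. It called 0 without INT male 1, INT male 2 or NINT male 1, with 1720, 1535 and 1847 genes at an unadjusted p under 0.05. It called 1 without NINT male 2 and 4 without NINT male 3. DESeq2 called 934 genes, 459 higher and 475 lower. The fit without the 4 male libraries above 500 CPM of yolk protein genes left 1 NINT male, so its loss of calls says little. None of the 6 genes kept its call in every fit, which follows from the fits that called 0 genes.

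**Figure D2:**
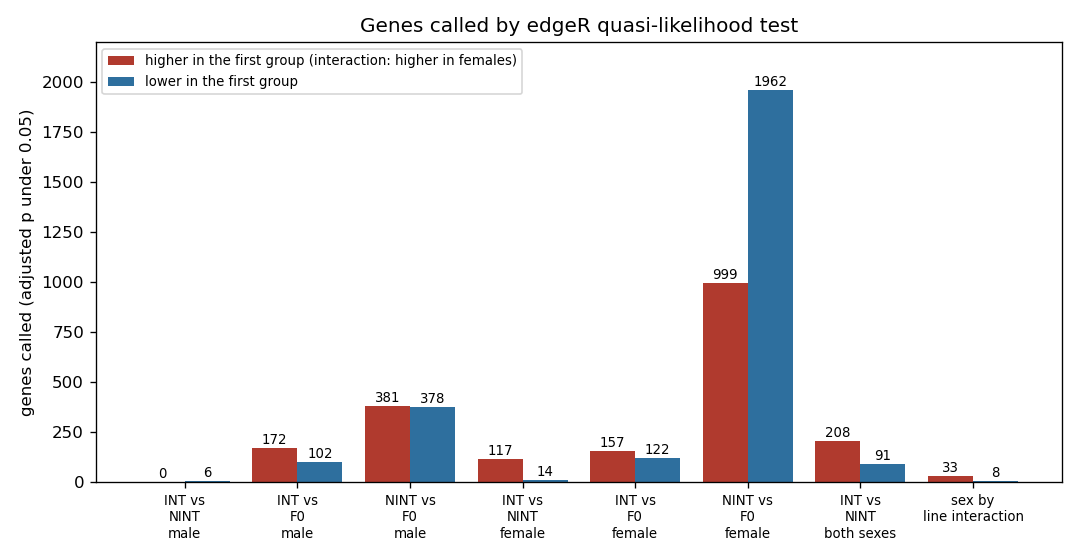
Number of genes called by edgeR at an adjusted p under 0.05 in each comparison, with genes higher and lower in the group named first as separate bars that start at 0. The counts run from 6 (INT and NINT males) to 2961 (NINT and F0 females).

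**Figure D3:**
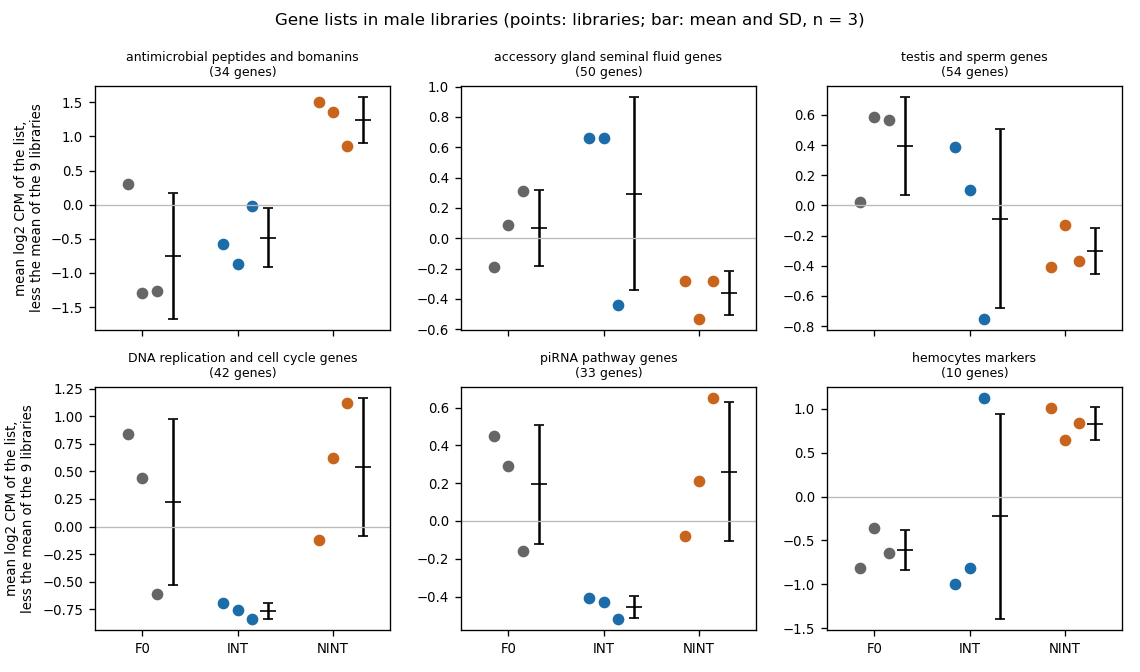
Mean log2 CPM of 6 gene lists in the 9 male libraries, minus the mean of those 9 libraries. Points are libraries, and bars show the mean and SD of the 3 libraries of a group; antimicrobial peptides are lower in INT than in NINT, with a median log2 fold change of -1.66.

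INT and NINT females differed in cuticle, muscle and mitochondrial genes, which lay higher in INT. The cuticle protein list, structural proteins of the insect exoskeleton, had 75 of 81 members above 0 with a median log2 of 2.17. The respiratory chain and ATP synthase list had 72 of 75 above 0 with a median of 0.79, and the muscle structural list 36 of 36 with a median of 1.26. Scp1, a sarcoplasmic calcium-binding protein gene, was at 1410 ± 692 CPM in INT and 54.6 ± 39.5 CPM in NINT (SD, n = 3). The small heat shock protein gene Hsp23 was lower, at 7.22 ± 2.15 against 38.8 ± 7.9 CPM.

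edgeR called 131 of 13169 genes, 117 higher and 14 lower in INT, with 1978 genes at an unadjusted p under 0.05 and 4956 genes (37.6%) with groups that did not overlap, where chance gives 10%. The largest named rises were CG13731 (3L, 17383636 to 17388956, 166-fold, adjusted p = 0.025), CG13026 (3L, 16724678 to 16726169, 71.2-fold, adjusted p = 0.0018) and Scp1 (2R, 2932595 to 2968052, 25.8-fold, adjusted p = 0.025). They were followed by the cytochrome oxidase subunit gene COX7AL2 (listed as CG34172, 16.6-fold, adjusted p = 0.03), CG4000 (10.7-fold, adjusted p = 0.039) and CG7409 (8.74-fold, adjusted p = 0.016). The largest falls were the chitin deacetylase gene Cda9 (2R, 17128480 to 17130334, 9.75-fold, adjusted p = 0.025), CG6277 (6.64-fold, adjusted p = 0.039), CG13905 (3L, 902898 to 903810, 5.97-fold, adjusted p = 0.013), Hsp23 (3L, 9381882 to 9382730, 5.37-fold, adjusted p = 0.03), CG5770 (3.83-fold, adjusted p = 0.025) and CG10910 (3.03-fold, adjusted p = 0.03).

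Cuticle protein genes rose as a list in INT females (adjusted p = 2.85e-17), with an adjusted p of 0.07 with an estimated correlation and 0.0037 by fry. In the list 3 genes were called over all genes and 49 when adjusted over the list alone, among them Ccp84Ag (16.4-fold, adjusted p = 0.0075) and Cpr65Au, at 40.2 ± 2.95 against 10.2 ± 2.4 CPM (adjusted p = 0.013). Respiratory chain and ATP synthase genes (adjusted p = 5.97e-14) and muscle structural genes (adjusted p = 2.79e-09) rose, with an adjusted p of 0.87 for both with an estimated correlation. The former list held 3 called genes and 19 when adjusted over the list alone. The called ones were the complex I subunit genes ND-B8 (listed as CG15434, 4.48-fold, adjusted p = 0.025), ND-MLRQ (CG32230, 304 ± 20.9 against 125 ± 5.51 CPM, adjusted p = 0.035) and ND-AGGG (CG40002, 153 ± 21.6 against 65.3 ± 6.13 CPM, adjusted p = 0.042). Among muscle genes 1 was called, the muscle LIM protein gene Mlp60A (3.09-fold, adjusted p = 0.035), and 16 when adjusted over the list alone. Act88F was at 596 ± 964 against 5.47 ± 1.94 CPM (adjusted p = 0.14), and within INT it was high in INT female 3. Muscle markers (median 1.98, 10 of 10 above 0, adjusted p = 0.00202) and glia markers (median 0.74, 10 of 10, adjusted p = 0.000466) rose with an adjusted p of 0.87 with an estimated correlation.

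Odorant-binding and chemosensory genes rose in INT females (69 of 102 above 0, median 0.45, adjusted p = 0.000466; 0.87 as the adjusted p with an estimated correlation), with 4 called over all genes and 19 over the list alone. The called ones were the odorant-binding protein genes Obp83a (3.17-fold, adjusted p = 0.011), Obp28a (3.42-fold, adjusted p = 0.036), Obp19a (2.28-fold, adjusted p = 0.03) and Obp57c (1.97-fold, adjusted p = 0.03). Acetylcholine and monoamine genes (34 of 37 above 0, median 0.65, adjusted p = 9.5e-05) and synaptic vesicle and active zone genes (29 of 35, median 0.49, adjusted p = 0.000946) rose, both with an adjusted p of 0.87 with an estimated correlation. The dopamine receptor gene Dop2R (3.29-fold, adjusted p = 0.03) and comt, the NSF ATPase of vesicle fusion (1.86-fold, adjusted p = 0.026), were the 2 called members. Phototransduction genes rose (25 of 35, median 0.38, adjusted p = 0.00497; 0.87 as the adjusted p with an estimated correlation), with retinin (6.04-fold, adjusted p = 0.025), a protein of the corneal lens, and Gbeta76C (2.3-fold, adjusted p = 0.044) called. This list lost its call without INT female 3 (0.087), NINT female 3 (0.13) or the 3 libraries above 1000 CPM of Act88F (0.078), and neuron markers (median 0.65, adjusted p = 0.0218; 0.87 as the adjusted p with an estimated correlation) had 0.14 and 0.095 without the same libraries. Glycolysis and tricarboxylic acid cycle genes rose (31 of 34, median 0.54, adjusted p = 0.00231; 0.87 as the adjusted p with an estimated correlation) and had 0.13 without INT female 3. Their only called member, Pdh (2.85-fold, adjusted p = 0.025), is a photoreceptor dehydrogenase of the visual pigment cycle and not a glycolytic enzyme. Cytosolic ribosomal protein genes rose (75 of 85, median 0.22, adjusted p = 0.000192; 0.87 as the adjusted p with an estimated correlation) with 0 called by edgeR over all genes or over the list alone.

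Heat shock proteins and chaperones fell in INT females (25 of 31 below 0, median -0.35, adjusted p = 7.3e-05), as did DNA replication and cell cycle genes (39 of 42, median -0.28, adjusted p = 0.000466), both with an adjusted p of 0.87 with an estimated correlation. Antimicrobial peptides and bomanins fell (29 of 33 below 0, median -1.05, adjusted p = 0.000466; 0.87 as the adjusted p with an estimated correlation), but had an adjusted p of 0.21 without NINT female 1. Their only called member, Drsl4, was 3.38-fold higher in INT (adjusted p = 0.026). In the immune recognition and melanization list, which was not called (median -0.17, adjusted p = 0.269), the crystal cell gene PPO2 (4.91-fold, adjusted p = 0.026) and PGRP-LF (2.34-fold, adjusted p = 0.047) rose. Hemocyte markers rose (median 0.41, 8 of 10 above 0, adjusted p = 0.0248; 0.87 as the adjusted p with an estimated correlation) and had 0.056 without INT female 3 and 0.085 without the 3 libraries above 1000 CPM of Act88F. Yolk, vitelline and chorion genes fell (17 of 25 below 0, median -0.28, adjusted p = 0.0356; 0.87 as the adjusted p with an estimated correlation), with 0.053, 0.11 and 0.32 without INT female 1, INT female 3 and NINT female 3, and 0.32 without those 3 libraries.

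The 131 calls became 15, 5 and 153 without INT females 1 to 3 and 4, 8 and 19 without NINT females 1 to 3. The log2 fold change ran from 4.24 to 5.45 for Scp1, 3.39 to 4.3 for COX7AL2 and 2.89 to 3.74 for CG7409 over the other fits. DESeq2 called 870 genes, 77% of them higher, a fit of the 6 compared libraries alone 1320, 62.3% of them higher, one of all 18 libraries 403, and the fit without the 3 female libraries above 1000 CPM of Act88F 839, of which 129 were among the 131.

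**Figure D4:**
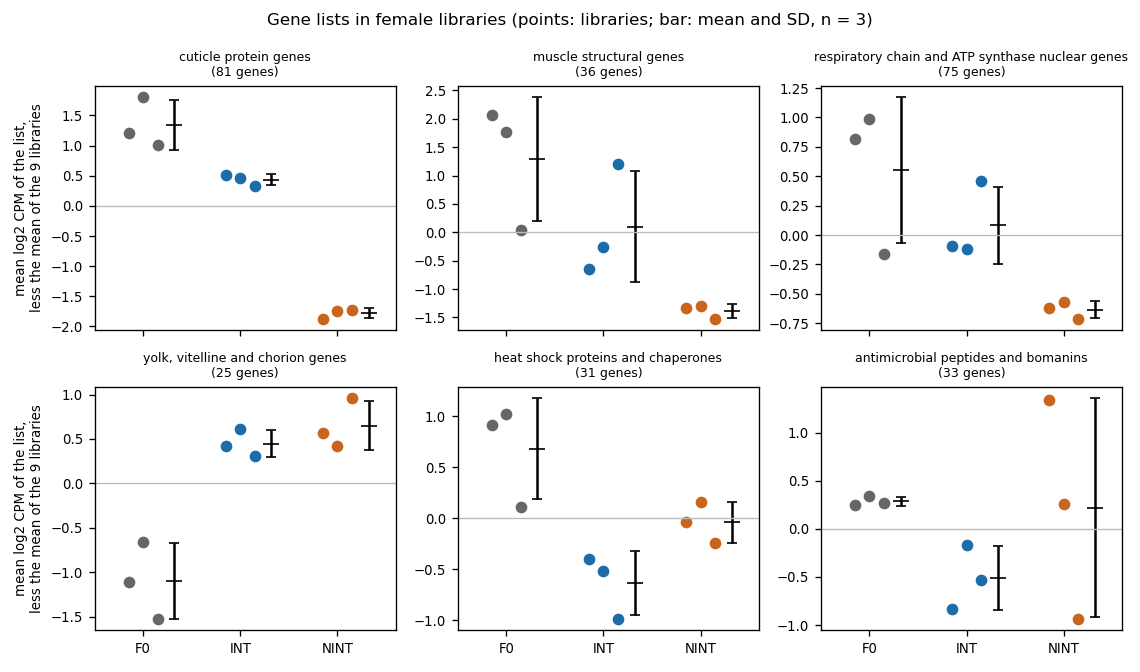
Mean log2 CPM of 6 gene lists in the 9 female libraries, minus the mean of those 9 libraries. Points are libraries, and bars show the mean and SD of the 3 libraries of a group; cuticle protein genes are higher in INT than in NINT, with a median log2 fold change of 2.17.

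A fit over both sexes asks for differences between INT and NINT that males and females share on average. neo, the gene of a zona pellucida domain protein, was higher in INT (log2 2.22, SE 0.22, adjusted p = 0.00078), as were CG12017 (log2 3.41, SE 0.38, adjusted p = 0.00079), CG14022 (log2 1.34, adjusted p = 0.00078), CG34134 (log2 1.23, adjusted p = 0.0016) and CG17127 (log2 2.04, adjusted p = 0.0029). CG13905 was lower (log2 -2.15, SE 0.23, adjusted p = 0.00078), as were CG2909 (log2 -0.77, adjusted p = 0.0044), CG14245 (log2 -1.54, adjusted p = 0.0052), CG44013 (log2 -1.32, adjusted p = 0.0067) and CG43773 (log2 -1.33, adjusted p = 0.0083). neo, CG12017, CG14022, CG17127 and CG43773 were also called in the interaction, CG43773 in only 4 of 19 other fits. CG17127, for example, was at 4.02 against 3.68 CPM in INT and NINT males and at 4.29 against 0.285 CPM in females. For CG12017 the NINT females held 1 count and the INT females 54, a ratio of 94.2 with a 95% interval of 16.2 to 3790. Antimicrobial peptides and bomanins fell (33 of 34 below 0, median -1.23, adjusted p = 2.01e-13) and synaptic vesicle and active zone genes rose (32 of 35 above 0, median 0.40, adjusted p = 2.48e-07), both with an adjusted p of 0.58 with an estimated correlation.

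This fit called 299 of 15304 genes, 208 higher and 91 lower in INT (69.6% higher), and 3165 had an unadjusted p under 0.05. With ribosomal RNA left out 269 genes were called and 56.9% were higher, and with no filter on low counts 242 and 58.3%. Respiratory chain and ATP synthase genes (79 of 83 above 0, median 0.49, adjusted p = 7.41e-15), muscle structural genes (35 of 36, median 0.86, adjusted p = 2.99e-10) and cuticle protein genes (78 of 86, median 1.36, adjusted p = 8.24e-11) rose, with an adjusted p of 0.58, 0.58 and 0.11 with an estimated correlation. DNA replication and cell cycle genes fell (42 of 42 below 0, median -0.76, adjusted p = 3.58e-13). So did piRNA pathway genes (29 of 33, median -0.42, adjusted p = 1.44e-06). Both had 0.58 with an estimated correlation, and the doubt given for males. DESeq2 called 1316 genes, 54.7% of them higher. Without the 7 libraries above the limits of 500 CPM of yolk protein genes and 1000 CPM of Act88F, 11 were called, 1 higher and 10 lower, of which 7 were among the 299. Without INT males 1 to 3 the count was 53, 55 and 2696. It was 119, 51 and 76 without NINT males 1 to 3. Without INT and NINT females 1 to 3 it was 171, 129 and 134, and 61, 85 and 144. The direction also depended on single libraries, with 22.7% higher without INT male 3, 50% without NINT female 3 and 82.5% without INT female 1.

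The calls of the male and female comparisons shared 0 genes in the same direction by edgeR, among 12930 genes in both fits with 6 called in males and 122 in females, too few in males to test the overlap. DESeq2 called 67 genes in both sexes, 52 in the same and 15 in opposite directions, of 934 in males and 870 in females. The overlap expected by chance was not computed. Across the 12930 genes the log2 fold changes of the sexes had a Pearson r of 0.12 and a Spearman rho of 0.25, and genes are not independent replicates. The interaction of sex and group, which tests the difference between the sexes itself, called 41 genes, and 1865 had an unadjusted p under 0.05. It called 5 to 702 without 1 library in turn, 505 by DESeq2 and 2, none of them among the 41, without the 7 libraries above the limits. Of the genes named by their p, the fold change of INT over NINT was greater in females than in males for CG12017, CG14022, CG17127, ImpE1 and neo and smaller for aly, Cda9, CAH5, CG43773 and CG5342. aly, known as a regulator of spermatocyte genes, and CG5342 held 0 counts in INT females and 106 and 26 counts in NINT females.

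Each F12 group was compared with the founders, where group cannot be told from rearing date or handling. In males the seminal fluid gene Acp24A4 (2L, 3693184 to 3693889) was at 365 ± 246 CPM in INT and 0.073 ± 0.126 CPM in F0 (SD, n = 3), 5010-fold higher (adjusted p = 0.0039), and its F0 counts all came from F0 male 1. Antisense RNA CR31084 (strand doubt as for CR44192) and the serine protease gene CG11313 were 204-fold and 71.6-fold higher (adjusted p = 0.00078 and 0.002). The metallothionein gene MtnB (3R, 20503102 to 20503618) was at 6.89 ± 0.512 against 109 ± 42.5 CPM, 15.8-fold lower (adjusted p = 0.0015). CG17147 (3L, 20223932 to 20225324) was 18.8-fold lower (adjusted p = 0.032) and the long non-coding RNA CR44344 13-fold lower (adjusted p = 0.0067). Some clock and opsin genes were higher in INT males, tim at 320 ± 27.1 against 143 ± 22.2 CPM and Rh4 at 148 ± 18.3 against 66.3 ± 6.79 CPM.

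edgeR called 274 of 15051 genes, 172 higher and 102 lower in INT than in F0 males, with 2874 at an unadjusted p under 0.05. Cytosolic ribosomal protein genes rose as a list (69 of 88 above 0, median 0.34, adjusted p = 3.42e-09), with 1 called, RpL18 (1.62-fold, adjusted p = 0.046), and 3 when adjusted over the list alone. Circadian genes rose (14 of 20, median 0.18, adjusted p = 0.0067), with tim (2.24-fold, adjusted p = 0.025), vri (1.78-fold, adjusted p = 0.025) and Pdp1 (1.68-fold, adjusted p = 0.025) called and 5 called when adjusted over the list alone, but had 0.052 without INT male 3. Eye markers rose (8 of 10, median 0.43, adjusted p = 0.00252), and phototransduction genes rose with a median of only 0.03 and a mean of 0.15 (adjusted p = 0.0134), with Rh4 (adjusted p = 0.0084), Rh6 (1.96-fold, adjusted p = 0.011) and ninaG (2.54-fold, adjusted p = 0.032) called and 12 when adjusted over the list alone. The phototransduction list had 0.13, 0.071 and 0.12 without F0 male 1, INT male 1 and INT male 2. Without the 4 male libraries above 500 CPM of yolk protein genes it had 0.55, and the eye marker list had 0.08. Learning and memory genes rose (32 of 40, median 0.17, adjusted p = 0.00156) and had 0.12 without those 4 libraries. The piRNA pathway genes fell (27 of 33 below 0, median -0.57, adjusted p = 4.03e-05), with tej (4.14-fold, adjusted p = 0.0096) and cuff (2.13-fold, adjusted p = 0.032) called and 8 when adjusted over the list alone. Each list named here had an adjusted p of 0.91 with an estimated correlation.

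Egg, ovary, cell division and germline lists, and perhaps piRNA genes, changed in INT against F0 males with the yolk protein sum. This sum was 1180 and 563 CPM in F0 males 1 and 2. Yolk, vitelline and chorion genes fell (25 of 25 below 0, median -5.71, adjusted p = 2.99e-05). DNA replication and cell cycle genes (40 of 42 below 0, median -0.92, adjusted p = 2.61e-06) and germline and female gonad genes (25 of 28, median -0.90, adjusted p = 0.000158) fell, with 0.71 and 0.41 without the 4 male libraries above 500 CPM, which leaves F0 male 3 alone in its group. Ovary markers fell (10 of 10, median -5.54, adjusted p = 0.00252) and had 0.058 without F0 male 1. Testis and sperm genes fell (49 of 54 below 0, median -0.46, adjusted p = 0.000158), and testis markers fell (10 of 10, median -0.48, adjusted p = 0.0312), with 0.46 and 0.51 without INT male 3 and, for the markers, 0.069 and 0.089 without F0 males 2 and 3. Each of these lists had an adjusted p of 0.91 with an estimated correlation. The P450 gene Cyp6a8 (19.7-fold, adjusted p = 0.01) and the lysozyme gene LysP (4.9-fold, adjusted p = 0.026) rose, in lists that lost their calls (adjusted p = 0.0379 for both) without INT male 3, at 0.27 and 0.89, or without F0 male 2, at 0.069 and 0.1. The P450 list had 0.079 without F0 male 1 and 0.18 without the 4 libraries, and the lysozyme gene's list, immune recognition and melanization, 0.14 without F0 male 3. Both lists had 0.063 without ribosomal DNA loci, SteXh and 7SL RNA, both turned direction without INT male 3, and both had an adjusted p of 0.91 with an estimated correlation.

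The 274 calls became 133, 28 and 66 without F0 males 1 to 3 and 131, 74 and 482 without INT males 1 to 3. Of these, 63.3% to 86.5% were higher. The log2 fold change of CG11313 ran from 5.73 to 7.31 over the other fits, that of CG17147 from -4.92 to -3.74, of Cyp6a8 from 3.59 to 4.65 and of LysP from 2.04 to 2.93. DESeq2 called 1416 genes, 52.1% of them higher, a fit of the 6 compared libraries 45, and edgeR called 0 (611 at an unadjusted p under 0.05) without the male libraries above 500 CPM of yolk protein genes, with 1 F0 male left.

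NINT males differed from F0 males in immune, detoxification and reproductive genes. Antimicrobial peptides and bomanins were higher in NINT, with 32 of 34 above 0 and a median log2 of 1.58. The cecropin gene CecA1 (3R, 30210874 to 30211273) was at 81.8 ± 7.05 against 27.4 ± 2.26 CPM and PGRP-SB1, a peptidoglycan recognition protein gene, at 92 ± 30.2 against 14.1 ± 8.26 CPM (SD, n = 3). Testis and sperm genes were lower, with 51 of 54 below 0 and a median of -0.86, and seminal fluid genes with 44 of 50 below 0 and a median of -0.66. Acp24A4 was again far above F0, at 122 ± 17.1 CPM (1680-fold, adjusted p = 0.0044).

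edgeR called 759 of 15051 genes, 381 higher and 378 lower in NINT, with 4804 at an unadjusted p under 0.05 and 7279 genes (48.4%) with groups that did not overlap, where chance gives 10%. The antimicrobial list rose (adjusted p = 2.43e-12), with 9 called higher and 1 lower over all genes and 24 and 1 when adjusted over the list alone. CecA1 (2.98-fold, adjusted p = 0.0037) and BomBc1 (3.43-fold, adjusted p = 0.0098) were among them. Immune recognition and melanization genes (37 of 47 above 0, median 0.86, adjusted p = 0.000182) and hemocyte markers (10 of 10, median 1.08, adjusted p = 0.000497) rose, with PGRP-SB1 at 6.51-fold (adjusted p = 0.018). Turandot stress genes rose (4 of 6, median 1.06, adjusted p = 0.023), with TotM (11.8-fold, adjusted p = 0.012) and TotA (2.55-fold, adjusted p = 0.047) called, but had 0.18 without F0 male 1. Glutathione transferase and cytochrome P450 genes rose (92 of 115, median 0.49, adjusted p = 2.19e-05) with 8 called. They included Cyp6a8 (16.8-fold, adjusted p = 0.009), GstD5 (6.31-fold, adjusted p = 0.029), GstD8 (6.18-fold, adjusted p = 0.035) and Cyp4ac3 (2.3-fold, adjusted p = 0.013). Lipid metabolism genes rose (28 of 37, median 0.30, adjusted p = 0.022), had 0.075 without F0 male 1, and held Npc1b (3.48-fold higher, adjusted p = 0.0074), a sterol transporter gene, and the fatty acid synthase gene FASN3 (3.79-fold lower, adjusted p = 0.032). Each of these lists had an adjusted p of 0.82 with an estimated correlation.

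Testis and sperm genes fell in NINT males (adjusted p = 2.62e-07), with 1 called lower over all genes and 13 over the list alone. gdl was 2.87-fold lower (adjusted p = 0.02), while bam, a germ cell differentiation factor, was 2.49-fold higher (adjusted p = 0.046). Testis markers fell (10 of 10, median -0.90, adjusted p = 0.00306), as did seminal fluid genes (adjusted p = 2.1e-05; 4 called lower and 1 higher, and 19 lower and 3 higher over the list alone) and accessory gland markers (10 of 10, median -0.73, adjusted p = 0.00327). Sfp96F was at 27 ± 7.79 against 80.9 ± 31.1 CPM (adjusted p = 0.028). Proteasome genes fell (31 of 32 below 0, median -0.24, adjusted p = 0.000138), with Prosalpha1 2.17-fold lower (adjusted p = 0.0049), and muscle structural genes fell (32 of 36, median -0.52, adjusted p = 0.000259). F0 male 1 stood apart in muscle markers, at 2.74 above the mean of the 9 males, while F0 males 2 and 3 were at -0.42 and -0.23 and NINT males at -0.54 to -0.25. Respiratory chain and ATP synthase genes fell (72 of 83, median -0.33, adjusted p = 0.000143), with COX6AL (listed as CG30093) 2.1-fold lower (adjusted p = 0.049), but had 0.18 without F0 male 1. Synaptic vesicle and active zone genes fell (25 of 35, median -0.14, adjusted p = 0.0187), with the potassium channel gene Sh 2.1-fold lower (adjusted p = 0.016), and had 0.096 and 0.067 without F0 male 3 and NINT male 3. Heat shock genes fell (22 of 31, median -0.75, adjusted p = 0.0344) and had 0.11, 0.1 and 0.19 without F0 male 1, F0 male 2 and NINT male 2. Without the 4 male libraries above 500 CPM of yolk protein genes the proteasome, respiratory, heat shock and Turandot lists had adjusted p of 0.12, 0.86, 0.45 and 0.1. Each of these lists had an adjusted p of 0.82 with an estimated correlation. Outside the lists CR31084 (281-fold) and CG11313 (168-fold) were higher, and CG34327 (126-fold), CG17147 (50.5-fold) and Npc2d (19.7-fold) lower, with adjusted p of 6e-04, 0.00094, 0.044, 0.012 and 0.0062.

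The 759 calls became 924, 107 and 84 without F0 males 1 to 3 and 116, 159 and 155 without NINT males 1 to 3. Of these, 39.6% were higher without F0 male 1 and 71% to 77.6% without each of the others. The log2 fold change of CG11313 ran from 6.96 to 8.53 over the other fits, that of CG17147 from -6.66 to -5.24, of CG34327 from -7.68 to -4.04, of FASN3 from -2.89 to -1.67, of PGRP-SB1 from 2.44 to 3.75 and of Sfp96F from -2.64 to -1.22. DESeq2 called 3125 genes, 38.8% of them higher, a filter of 5 CPM in 3 libraries left 408, a fit of the 6 compared libraries called 4839, and edgeR called 0 (766 at an unadjusted p under 0.05) without the male libraries above 500 CPM of yolk protein genes, where 1 library was left in both groups.

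INT females differed from F0 females in eggshell, heat shock and digestive genes. Yolk, vitelline and chorion genes were higher in INT, with 24 of 25 above 0 and a median log2 of 1.58. The chorion genes Cp16 and Cp18 were at 186 ± 45 against 19.4 ± 9.09 CPM and 390 ± 120 against 35.1 ± 31.4 CPM (SD, n = 3). Heat shock proteins and chaperones were lower, with 27 of 31 below 0 and a median of -0.89. Digestive enzyme genes were lower, among them the amylase gene Amy-d at 256 ± 13.2 against 876 ± 80.8 CPM. The serine protease gene CG7542 (3L, 17549826 to 17550658) was at 44.9 ± 3.9 against 0.449 ± 0.166 CPM.

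edgeR called 279 of 13169 genes, 157 higher and 122 lower in INT, with 2335 at an unadjusted p under 0.05. CG7542 was 100-fold higher (adjusted p = 7.6e-05), CG4757 20.4-fold (adjusted p = 0.014) and lcs 11.8-fold (adjusted p = 0.027). The protease gene Ser12 held 0 counts in the F0 females and was at least 173-fold higher against a floor of 3 counts over the group (adjusted p = 0.0062). CG17147 was 28.2-fold lower (adjusted p = 0.0038) and CG6277 22-fold lower (adjusted p = 0.007). The yolk, vitelline and chorion list rose (adjusted p = 1.1e-12) with 11 called and 14 when adjusted over the list alone. Among them were Cp18 (11.1-fold, adjusted p = 0.034), Cp16 (9.6-fold, adjusted p = 0.014), Cp7Fa (6.55-fold, adjusted p = 0.0062), CG11381, CG13083 and Femcoat. Ovary markers rose (10 of 10, median 0.51, adjusted p = 8.05e-05). The adjusted p with an estimated correlation was 0.48 for the former and 0.25 for the latter. Turandot stress genes rose (3 of 4, median 1.99, adjusted p = 0.00146), with 0.12 without F0 female 3, and cytosolic ribosomal protein genes rose (77 of 85, median 0.29, adjusted p = 3.58e-07), with adjusted p of 0.6 and 0.61 with an estimated correlation.

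Heat shock genes fell in INT females (adjusted p = 2.01e-07; 0.48 as the adjusted p with an estimated correlation), with 8 called and 14 when adjusted over the list alone. Hsp68 was 13.1-fold lower (adjusted p = 0.019), and the copies Hsp70Ba, Hsp70Bb, Hsp70Bbb and Hsp70Bc were 18.2-fold to 19.5-fold lower (adjusted p = 0.019 each). These copies are near-identical, so they are not separate observations. Digestive enzyme genes fell (47 of 65 below 0, median -0.55, adjusted p = 5.87e-06), with 12 called lower and 2 higher and 25 and 2 when adjusted over the list alone. Amy-d (3.42-fold, adjusted p = 0.0038), Mal-A3 (5.49-fold, adjusted p = 0.036) and Mal-A4 (10.6-fold, adjusted p = 0.019) act on starch and sugars. Midgut markers fell (7 of 10, median -0.57, adjusted p = 0.00274) and had 0.22 without F0 female 3. Glycolysis and tricarboxylic acid cycle genes fell (33 of 34, median -0.77, adjusted p = 1.68e-08), with Mdh1 (1.59-fold, adjusted p = 0.034) called. Antimicrobial peptides and bomanins (27 of 33, median -0.83, adjusted p = 0.000147) and immune recognition genes (32 of 46, median -0.38, adjusted p = 0.000268) fell, with LysX (4.69-fold, adjusted p = 0.021) and PGRP-SC2 (2.75-fold, adjusted p = 0.019) called in the latter. Glutathione transferase and cytochrome P450 genes fell (75 of 113, median -0.34, adjusted p = 0.00211), with 9 called lower and 5 higher. The adjusted p with an estimated correlation was 0.61 for each of the lists from digestive enzymes to P450 genes.

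Other lists moved with the Act88F level of F0 females 1 and 2. Muscle structural genes (33 of 36 below 0, median -1.08, adjusted p = 4.14e-06), muscle markers (10 of 10, median -1.82, adjusted p = 0.000517), cuticle protein genes (67 of 81, median -0.66, adjusted p = 8.05e-05) and respiratory chain genes (68 of 75, median -0.57, adjusted p = 2.01e-07) fell, the last with ND-B8 2.78-fold lower (adjusted p = 0.033); the adjusted p with an estimated correlation was 0.61, 0.61, 0.48 and 0.61. Without the 3 female libraries above 1000 CPM of Act88F the respiratory list had an adjusted p of 0.96, and DNA replication and cell cycle genes turned from a rise (41 of 42, median 0.33, adjusted p = 8.67e-06; 0.61 as the adjusted p with an estimated correlation) to a fall (adjusted p = 0.0044). Neuron markers (median -0.75, adjusted p = 0.0105), learning and memory genes (median -0.36, adjusted p = 0.00429), synaptic genes (median -0.42, adjusted p = 0.000317) and acetylcholine and monoamine genes (median -0.69, adjusted p = 0.000405) fell, with 0.61 for each with an estimated correlation. They had adjusted p of 0.28, 0.18, 0.22 and 0.27 without F0 female 1 and 0.62, 0.81, 0.59 and 0.14 without the 3 libraries.

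The 279 calls became 209, 39 and 4310 without F0 females 1 to 3 and 58, 30 and 265 without INT females 1 to 3. Of these, 52.2% to 72.4% were higher. The log2 fold change of Hsp68 ran from -4.11 to -1.8 over the other fits, that of the 4 Hsp70 copies from -4.79 to -2.09, of Cp18 from 3.06 to 5.36, of lcs from 2.65 to 4.68, of CG17147 from -5.53 to -4.53, of CG6277 from -5.29 to -3.99 and of Mal-A4 from -4.41 to -3.06. DESeq2 called 983 genes, 44.4% of them higher, a fit of the 6 compared libraries 32, one of all 18 libraries 421, and the fit without the 3 libraries above 1000 CPM of Act88F 166, of which 93 were among the 279.

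NINT females differed from F0 females in cuticle, muscle, energy and eggshell genes. The first 3 were lower in NINT, and eggshell genes were higher. Act88F was at 5.47 ± 1.94 against 3020 ± 2370 CPM and the sarcoplasmic calcium pump gene SERCA (listed as Ca-P60A) at 381 ± 52.5 against 2780 ± 1480 CPM (SD, n = 3). Cytochrome c (Cyt-c-p) was at 267 ± 40.6 against 1220 ± 704 CPM and the glycolytic gene Gapdh1 at 183 ± 6.1 against 731 ± 312 CPM. Cda9 was at 16.9 ± 0.603 against 0.179 ± 0.181 CPM.

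edgeR called 2961 of 13169 genes, 999 higher and 1962 lower in NINT, with 5320 at an unadjusted p under 0.05. Cuticle protein genes fell (77 of 81 below 0, median -3.42, adjusted p = 1.97e-14; 0.12 as the adjusted p with an estimated correlation, 0.00054 by fry), with 47 called lower and 1 higher and 62 and 1 when adjusted over the list alone. Among them Cpr92F, Cpr47Ea and Ccp84Ag had log2 fold changes of -12.18, -9.75 and -4.92 (adjusted p = 0.015, 0.0053 and 0.00075), and Cpr97Ea held 0 counts in NINT and was at least 2200-fold lower (adjusted p = 0.037). Acp1, a cuticle protein gene outside the list, was 7000-fold lower (adjusted p = 0.013), and CG13043 held 0 counts in NINT and was at least 858-fold lower (adjusted p = 0.015). Muscle structural genes fell (35 of 36, median -2.34, adjusted p = 3.79e-11), with 30 called and 33 over the list alone. Among them were fln (812-fold, adjusted p = 0.017), Act88F (550-fold, adjusted p = 0.019), TpnC4 (236-fold, adjusted p = 0.0091) and SERCA (7.28-fold, adjusted p = 0.0083). Muscle markers fell (10 of 10, median -3.93, adjusted p = 7.47e-05). Respiratory chain and ATP synthase genes fell (70 of 75, median -1.35, adjusted p = 1.38e-14), with 61 called and 65 over the list alone. Among them were ND-B8 (12.4-fold, adjusted p = 0.00093), ATPsyn-gamma (4-fold, adjusted p = 0.017) and Cyt-c-p (4.55-fold, adjusted p = 0.025). Glycolysis and tricarboxylic acid cycle genes fell (33 of 34, median -1.27, adjusted p = 6.2e-09), with 27 called and 31 over the list alone, among them kdn, the citrate synthase gene (6-fold, adjusted p = 0.03). The muscle, respiratory and glycolysis lists had an adjusted p of 0.62 with an estimated correlation and 0.043 by fry, and F0 females 1 and 2 held the highest Act88F levels.

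Yolk, vitelline and chorion genes rose in NINT females (22 of 25 above 0, median 1.77, adjusted p = 5.89e-09), with 15 called and 16 over the list alone, among them Cp18 (13.7-fold, adjusted p = 0.0099) and Cp7Fa (11.2-fold, adjusted p = 0.00093). Ovary markers rose (9 of 10, median 0.66, adjusted p = 0.00139). With an estimated correlation the adjusted p was 0.62 and 0.29. The piRNA pathway genes (27 of 33, median 0.43, adjusted p = 0.000434), germline and female gonad genes (20 of 28, median 0.40, adjusted p = 0.0117) and DNA replication genes (42 of 42, median 0.63, adjusted p = 5.54e-08) rose, with 0.62 for each with an estimated correlation. vret (2.07-fold, adjusted p = 0.039), exu (2.11-fold, adjusted p = 0.027) and CycB3 (1.96-fold, adjusted p = 0.033) were among the 7, 4 and 4 called as higher. Without the libraries above 1000 CPM of Act88F these lists had adjusted p of 0.31, 0.49 and 0.45, and the germline list had 0.055 and 0.06 without F0 female 2 and NINT female 3.

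Lists of nerve genes fell in NINT females. Acetylcholine and monoamine genes had 34 of 37 below 0 (median -1.36, adjusted p = 8.91e-07), with 20 called lower. They included ple, the tyrosine hydroxylase of dopamine synthesis (11.2-fold, adjusted p = 0.037), Dop2R (4.54-fold, adjusted p = 0.0036) and ebony (e, 48.7-fold, adjusted p = 0.024); ple and ebony also act in cuticle pigmentation. Synaptic vesicle and active zone genes fell (31 of 35, median -0.90, adjusted p = 1.08e-05), with 17 called, among them brp (3.95-fold, adjusted p = 0.02) and para (5.09-fold, adjusted p = 0.017), and learning and memory genes fell (30 of 40, median -0.48, adjusted p = 0.00657) with 15 called lower and 2 higher. Glia markers (median -1.02, adjusted p = 0.00178) and neuron markers (median -1.47, adjusted p = 0.00171) fell. Odorant-binding and chemosensory genes fell (65 of 102, median -0.62, adjusted p = 0.021), with Obp99b 60.2-fold lower (adjusted p = 0.013), but had 0.18 and 0.061 without F0 female 1 and NINT female 1. Digestive enzyme genes (48 of 65, median -0.80, adjusted p = 0.000561) and midgut markers (8 of 10, median -0.83, adjusted p = 0.00745) fell, with 0.062 and 0.13 without F0 female 3. Each of these lists had an adjusted p of 0.62 with an estimated correlation, and without the libraries above 1000 CPM of Act88F the synaptic, learning, neuron and odorant lists had adjusted p of 0.056, 0.26, 0.11 and 0.95.

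The 2961 calls became 1660, 631 and 6851 without F0 females 1 to 3 and 585, 656 and 583 without NINT females 1 to 3. Many folds given above moved between the fits. The log2 fold change ran from -3.05 to -0.47 for kdn, -2.6 to -0.61 for Cyt-c-p, -2.36 to -0.77 for ATPsyn-gamma, -2.36 to -0.61 for brp, -2.73 to -0.96 for para, -4.01 to -0.2 for ple, -6.15 to -2.01 for ebony and -6.48 to -0.93 for Obp99b. It ran from -9.74 to -5.67 for Act88F, -10.77 to -6.53 for fln, -8.38 to -5.32 for TpnC4, -3.23 to -1.6 for SERCA, -2.3 to -1.08 for Gapdh1, -14.24 to -8.74 for Acp1, -10.27 to -6.62 for Cpr47Ea, 5.45 to 7.77 for Cda9, 3.34 to 5.43 for Cp18 and 0.41 to 1.55 for vret. DESeq2 called 4503 genes, 1873 of the called genes had a fold change of at least 2-fold, a fit of the 6 compared libraries called 1224, and the fit without the 3 libraries above 1000 CPM of Act88F 867, of which 704 were among the 2961 while 7 of the 2961 changed sign.

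The changes of INT and NINT from F0 overlapped. In males 205 genes were called the same way in both comparisons, 138 higher and 67 lower than in F0, and 0 in opposite ways. Independent lists would share 4.4 and 2.6. In females 218 were, 117 higher and 101 lower, where 11.9 and 18.2 were expected. Both comparisons used the same 3 F0 libraries, too few to split, so they may give part of the overlap. Simulations with shared controls and no change gave 0 shared calls. Their r between fold changes was 0.50 in males and 0.51 in females (0.67 and 0.69 in the data). F0 libraries differed in whole gene lists, so their part stays unknown. CG17147 was shared and lower than in F0 in both sexes. Of the 131 calls between INT and NINT females, 89 were also calls for NINT against F0 alone, 29 for INT alone, 8 for both and 5 for neither. Of the 6 in males, 5 were for NINT alone and 1 for both. The tests share libraries and NINT had more calls against F0, so which moved is not shown.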

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

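Each explanation and test in this part was chosen after the results were seen.

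The interaction of sex and group called 41 genes. The values below are log2 fold changes of INT over NINT in females minus those in males. ImpE1 (4.80, adjusted p = 0.0021), CG12017 (5.20), CG17127 (3.68), neo (3.20) and CG14022 (2.07) had positive differences. aly (-7.95, adjusted p = 0.031), CG5342 (-6.28, adjusted p = 0.047), Cda9 (-3.37, adjusted p = 0.018), CAH5 (listed as CG18673, -3.08, adjusted p = 0.035) and CG43773 (-2.22, adjusted p = 0.047) had negative ones. aly and CG5342 held 0 counts in INT females, so their fitted values are no bounds, and CG12017 rests on 1 count in NINT females.

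The list medians of the interaction, which are differences of fold changes as above, included lists of male and female reproduction. Ovary markers (5.04), yolk, vitelline and chorion genes (4.62), fat body markers (3.40), germline and female gonad genes (0.74), DNA replication and cell cycle genes (0.88) and piRNA pathway genes (0.36) had positive medians. Male accessory gland markers (-2.81), seminal fluid genes (-2.16) and testis and sperm genes (-0.54) had negative ones. Each of these lists had an adjusted p of 0.73 with an estimated correlation. The yolk list had 0.71 without the 7 doubted libraries. Seminal fluid genes had 0.75 and male accessory gland markers 0.97 without NINT female 1, which held 71.26 CPM of Acp36DE. The accessory gland markers lost their call without 9 of the 12 libraries in turn, and the testis and sperm genes without 3, with up to 0.19. Germline genes lost their call without INT male 3 or NINT male 3, with up to 0.12. The piRNA pathway genes had 0.1 without NINT male 3 and 0.51 without the doubted libraries.

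Cuticle protein genes had a median of 2.59 in the interaction (adjusted p = 4.03e-16), with an adjusted p of 0.02 with an estimated correlation. Muscle markers (1.67), muscle structural genes (0.85), respiratory chain genes (0.47), glycolysis and tricarboxylic acid cycle genes (0.45), glia markers (0.52) and acetylcholine and monoamine genes (0.34) had positive medians, with 0.73 for each with an estimated correlation. Without INT female 3 the muscle markers had an adjusted p of 0.46, the muscle structural genes 0.1, the respiratory chain genes 0.054, the glycolysis list 0.1 and the acetylcholine list 0.13, and the muscle markers also lost their call without INT male 3. Turandot genes (1.65), hemocyte markers (1.15), fat body storage genes (0.81), antimicrobial peptides and bomanins (0.62) and glutathione transferase and P450 genes (0.21) had positive medians, and heat shock genes (-0.66) and proteasome genes (-0.25) negative ones. The P450 list lost its call without 6 of the 12 libraries in turn, with up to 0.43, and the antimicrobial list had 0.29 without NINT female 3. With an estimated correlation these had adjusted p of 0.44 to 0.73.

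Regroupings of the libraries were no clean measure of chance. Over both sexes 2 of 100, the real one included, called at least 299 genes. The other, at 418, only exchanged INT male 3 and NINT male 2. For the interaction 4 of 100 reached 41, with 173 as the highest other. That one joined INT males 1 and 2 and NINT male 3 with the NINT females.

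Within 1 sex only 10 regroupings exist per pair, too few to tell the count from chance. INT against NINT males had 6 calls and at most 0 in another regrouping, INT against F0 males 274 and 0, NINT against F0 males 759 and 3, INT against NINT females 131 and 0, and NINT against F0 females 2961 and 0, so 1 of 10 reached the count in each. For INT against F0 females 2 of 10 did, and the other called 1031 genes against 279. That regrouping put F0 females 1 and 2 with INT female 3, which points to a structure of the samples other than the groups.

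Ovary and yolk genes were high in F0 males 1 and 2 and NINT males 2 and 3, and this could come from RNA of female flies in those libraries. Then the female-specific genes of a library would stand at 1 ratio to their female level. The share within 4-fold of that ratio was 87.2%, 53.2%, 76.3% and 79.7% in the 4 libraries, and the lowest, 53.2% in F0 male 2, lies between the bounds set for and against the explanation, so it stays open. Expression by F0 males as a group was not met, since F0 male 3 had a sum of only 6.8 CPM, below the INT males. Expression by NINT males stays possible, since their lowest sum was 136 CPM against a highest of 14.7 in INT males.

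INT male 3 had a mean correlation of 0.943 with the other INT males and 0.963 with the NINT males. A swap of its label with a NINT male was not met, because 0 NINT males were closer to INT males 1 and 2 than to the other NINT males. A NINT male labelled as INT could not be told apart from a true difference among INT males, because a score over the genes called in females did not separate the groups in males (-0.21). A smaller share of male reproductive tissue would shift all other tissues alike, but hemocyte markers shifted by 1.89 (SE 0.45) more than neuron markers, so it was not met as the only cause. Testis and accessory gland markers lay 1.07 below INT males 1 and 2 in INT male 3, so a part for it, or a change in hemocytes, stays open. A difference in infection state between vials remains open, as untested.

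F0 females 1 and 2 and INT female 3 held high levels of flight muscle and cuticle genes. A smaller share of ovary would raise all other tissues alike, but muscle markers lay above eye markers by at least 1.45 (SE 0.46) in these libraries. Younger flies remain possible, since larval storage genes lay above the mean of the 9 females by at least 1.23 in each of the picked libraries. The 5 larval genes were picked after these libraries were seen, and 3 of them were among the called genes. Differences in the handling or storage of the flies were not tested.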

How the results depend on the processing

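The fits without the male libraries above 500 CPM of yolk protein genes, without the female libraries above 1000 CPM of Act88F and without the entries of ribosomal DNA loci, SteXh and 7SL RNA were chosen after the results were seen, and the others before.

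DESeq2, which brings its own scaling and set of tested genes, moved every count. It called 934 genes for INT against NINT males (6 by edgeR), 1416 for INT against F0 males (274), 3125 for NINT against F0 males (759), 870 for INT against NINT females (131), 983 for INT against F0 females (279), 4503 for NINT against F0 females (2961), 1316 over both sexes (299) and 505 for the interaction (41). In simulated data DESeq2 made 22 to 46 false calls and edgeR 1 to 10. With DESeq2 the calls for INT against NINT and also for NINT against F0 alone were 349 in males (5) and 567 in females (89). INT and NINT against F0 shared 772 in males (205) and 731 in females (218). By DESeq2 both sexes shared 52 calls in the same direction (0 by edgeR), with no chance level computed.

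Leaving out 1 library moved the counts, and the cause was not tested. The range was 0 to 3956 for INT against NINT males, 28 to 482 for INT against F0 males, 84 to 924 for NINT against F0 males, 4 to 153 for INT against NINT females, 30 to 4310 for INT against F0 females and 583 to 6851 for NINT against F0 females. It was 51 to 2696 over both sexes and 5 to 702 for the interaction. The highest counts came without INT male 3 or F0 female 3, except for 924 without F0 male 1 and 153 without INT female 3.

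Without the male libraries above 500 CPM of yolk protein genes the counts were 0 in each of the 3 male comparisons. Without the female libraries above 1000 CPM of Act88F they were 839, 166 and 867 for INT against NINT, INT against F0 and NINT against F0 females. These fits left 1 library in F0 males, NINT males and F0 females, so a loss of calls says little. Without both sets 11 genes were called over both sexes, 7 of them among the 299, and 2 in the interaction, none of them among the 41. The lists called for INT against F0 males fell from 15 to 8. The yolk, vitelline and chorion list turned from a fall to a rise in INT against F0 males (adjusted p = 0.0352), which follows from leaving libraries out by their yolk genes. DNA replication and cell cycle genes turned from a rise to a fall in INT against F0 females (adjusted p = 0.00439). The cause was not tested.

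A fit of only the 6 libraries compared called 45 genes for INT against F0 males, 4839 for NINT against F0 males, 1320 for INT against NINT females, 32 for INT against F0 females and 1224 for NINT against F0 females. The fit of all 18 libraries called 403 for INT against NINT females and 421 for INT against F0 females. A filter of 5 CPM in 3 libraries left 408 genes for NINT against F0 males and 26 in the interaction. The interaction had 22 genes with RLE scaling (68.2% shifted upward, against 80.5%), 21 with no filter and 25 without ribosomal RNA. Of the called genes, 1873 had a fold change of at least 2 for NINT against F0 females and 1.6e+02 over both sexes.

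With the replicate number as a block, the counts were 0 for INT against NINT males, 63 for INT against F0 males, 149 for NINT against F0 males, 3 for INT against NINT females, 80 for INT against F0 females, 850 for NINT against F0 females, 33 over both sexes and 0 for the interaction. The correlation between libraries of the same number ran from -0.456 to 0.439 in females and from -0.411 to 0.407 in males, so the numbers do not pair the samples and the block is no better model.

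With an estimated correlation 0 lists were called in each comparison except 1 in the interaction. fry called 0 lists in each of the male comparisons, 1 for INT against NINT females, 5 for INT against F0 females, 13 for NINT against F0 females, 1 over both sexes and 1 in the interaction. camera with the preset correlation had called 25, 15, 17, 17, 24 and 19 in the 6 comparisons by sex, with males first, and 24 over both sexes and 23 in the interaction.

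Of the named called genes, 0 turned direction in a fit. None of 6, 17 and 23 kept their call in every fit in the male comparisons, 1 of 30 did for INT against NINT females, 4 of 27 for INT against F0 females and 20 of 61 for NINT against F0 females. Over both sexes and in the interaction it was 0 of 10 each.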

Other observations

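No explanation in this part was fixed before the results were seen.

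Some lists not described so far moved by small amounts. Cytosolic ribosomal protein genes lay higher in NINT than in F0 males (75 of 88 above 0, median 0.23, adjusted p = 7.33e-05) with 0 called by edgeR over all genes or the list alone, and with an adjusted p of 0.82 with an estimated correlation. Lipid metabolism genes were lower in INT than in NINT males (median -0.25, 28 of 37 below 0, adjusted p = 0.0251; 0.69 as the adjusted p with an estimated correlation), and had 0.46, 0.22 and 0.078 without INT male 1, INT male 2 and NINT male 1. Autophagy genes were lower in INT over both sexes (median -0.14, 19 of 27 below 0, adjusted p = 0.037; 0.58 as the adjusted p with an estimated correlation), and had 0.052, 0.094 and 0.056 without INT male 1, INT male 2 and INT female 3. Fat body storage genes were lower in INT than in F0 females (median -0.76, 23 of 28 below 0, adjusted p = 0.0105; 0.61 as the adjusted p with an estimated correlation), and had 0.097 and 0.1 without F0 females 1 and 2 and 0.13 without the 3 libraries above 1000 CPM of Act88F.

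The series title concerns longevity, and the lists nearest to it were not called in any comparison. Lifespan and antioxidant genes had a lowest adjusted p of 0.0676, over both sexes, and insulin and TOR signalling genes one of 0.167. Malpighian tubule markers reached 0.0813, female reproductive tract markers 0.153 and ejaculatory duct and bulb markers 0.195. Of the founder genotype genes, which reached 0.34, w had a log2 of 0.06 (adjusted p = 0.93), flr -0.02 (0.95) and mwh 0.40 (0.57) between INT and NINT females. Against F0 females, mwh was 2.64-fold lower in NINT (adjusted p = 0.021).

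The learning and memory list was called higher in INT over both sexes (30 of 40 above 0, median 0.23, adjusted p = 0.00244; 0.58 as the adjusted p with an estimated correlation). It had 0.064 without INT male 3 and 0 called genes by edgeR. In females alone it was not called (median 0.27, adjusted p = 0.175).

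The lower level of antimicrobial peptide genes in INT than in NINT males may be a difference between the groups or a difference in infection among a few vials. The list kept its call without each library in turn, and INT males lay near F0 males (median 0.12, adjusted p = 0.455) while NINT males lay above F0. INT male 3 shifted by 1.89 (SE 0.45) more in hemocyte than in neuron markers, so at least 1 library differed from its group in immune tissue. Whether the vials were infected was not tested.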
